A study of Mus musculus with 4 samples.

How the data were processed

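Total RNA of PTC2+ and PTC2− cells from the kidney-ureter junction of SV/129 embryos at E13.5 was amplified with a NuGEN Ovation kit and made into libraries with Nextera XT, per the labels' protocols. Per the file headers the 4 libraries shared 1 sequencing lane. Per the submitters' processing notes, TopHat2 2.0.5, TopHat and Cufflinks 2.0.0 were used with the genome build mm9. Which tool counted reads, with which gene models, is not given in the sources used here. The deposited values are normalized RPKM per the file headers and labels, and the formula of the further normalization is not given in the sources used here. The column sums lie between 283806 and 288752 NRPKM.

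The value of 1 read was estimated from short genes, as the most common low value after multiplication by gene length. Only pseudogenes and genes with names beginning with Olfr, Gm or Vmn, under 3000 bp, were used. In PTC2+ replicates 1 and 2, 34 of 121 and 37 of 132 low values lay within 0.5% of it. In PTC2− replicates 1 and 2 it was 27 of 132 and 17 of 89. Smaller clusters lay at fractions of it. Most low values did not lie at the step, so it is an estimate. If the values were plain RPKM, these steps would stand for 1164060, 1222990, 1550790 and 1139900 reads in PTC2+ replicates 1 and 2 and PTC2− replicates 1 and 2. Whole reads were not recovered for nearly all genes, so no count model was used.

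Of the 36186 row identifiers, 33006 matched the NCBI gene table of GRCm38, and 32555 of these carried a listed symbol that is the current symbol or a synonym. 27 symbols had been turned into calendar dates, 2 of them inside the segments. The gene table served for names, gene class, length and order along chromosomes; no coordinate of it is given, because the build differs from mm9.

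Whether names fit values was checked with genes that every cell uses (863 genes such as those of the ribosome, proteasome and spliceosome) and with 1550 tissue-restricted genes. The pattern that picks constitutive genes was revised 3 times after its values had been seen. Outside the segments the share at 5 NRPKM or more was 33.8% with the version 1 pattern (340 genes), 37.7% with version 2 (1037 genes), 38.3% with version 3 (945 genes) and 37.9% with the version used (828 genes). Inside the segments the version 2 pattern had 46 of 47 genes at that level, and the other versions had every gene. Segments were the highest-scoring run of protein-coding rows other than the restricted genes per chromosome, with a score of 0.6 for a row averaging 20 NRPKM or more, -0.4 for another row, and a total over 10. The detection level, these scores and the total were set after scores per chromosome had been seen. The used runs scored 57.8, 42.6 and 20.4, and the next scored 7.6. With 10 NRPKM as the detection level 11 runs passed, several of them in mid-chromosome. With 40 NRPKM only shorter runs on chromosomes 19 and 16 passed, which hold 5 of the 20 named genes. Of these 5, 1 (Unc93b1) was named as higher and 4 as lower. Neither the choice of segments nor that of constitutive genes used the population labels. A pair of searches for a constant shift between gene positions and values gave no single shift and are not used here. A test of depth that compared constitutive genes inside and outside the segments was replaced after its result was seen, because the segments had been chosen on those values. For shallower PTC2− libraries, the bound that would exclude them was changed from 1 PTC2− library to both after the result was seen. The median difference of the myeloid list against each PTC2− library (1.21 for both) was then tried, and last the test on well-covered genes, first with named genes and then without them, chosen after those values were seen; its limits are order statistics of the median over genes, which are not independent.

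Values were tested as log2(NRPKM + 1) with limma 3.58.1 (lmFit and eBayes with a mean-variance trend, R 4.3.3) on rows at 1 NRPKM or more in at least 2 libraries. Differences are PTC2+ minus PTC2− on this scale, which understates the change of low genes. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05, over all rows, and again within the segments. The test, the filter, the naming rule, the gene lists and most alternatives were fixed before the data were examined. The restriction to segments, the adjustment within them, the fits on segment rows or protein-coding segment rows alone the other detection levels and the myeloid list without relatives of named genes were chosen after seeing the data.

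The naming rule took the 10 largest differences in each direction among rows with adjusted p under 0.05 and no overlap between populations, filled up from unadjusted p under 0.05, without predicted names; it was applied inside the segments. It also named Ptch1, Gli1, Hhip, a gene that is not reported here, and up to 4 members of each fixed list; list members outside the segments were not named. The 310 list members in 21 lists of cell types and pathways were tested with camera (preset correlation 0.01), camera with an estimated correlation, and fry, for lists with at least 3 tested rows.

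The fit was tested on simulated data with the real rows' means and the spreads that limma had drawn toward its trend, 20 draws a setting. Rows were drawn independently and without a floor at 0, so the shares below may be more favourable than in the data. With 200 of 11807 rows changed, 1.52% were recovered at 2-fold, 58.3% at 4-fold and 94.0% at 8-fold. With 40 of 706 segment rows changed, 47.6, 89.2 and 98.8% were recovered. The mean share of false calls was 24.1, 8.99 and 7.53% over all rows and 8.96, 6.83 and 5.61% in segments at these folds, above the nominal 5%. With no change, 7 of 20 draws over all rows and 1 of 20 in segments gave a call. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and matplotlib 3.10.9 for plots. Alternatives were pseudocounts of 0.1 and 5, no filter, a filter of 5 NRPKM, equal medians, quantile normalization, no trend, the replicate number as a block and leaving out each library.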

Results

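RNA was sequenced from cells of the mouse kidney-ureter junction at E13.5. The embryos lacked Ptch1, the receptor that holds hedgehog signalling in check, in the metanephric mesenchyme, the tissue that surrounds the budding ureter. Cells were sorted with an antibody against PTC2 into a PTC2+ and a PTC2− population. Each population has 2 libraries, named replicate 1 and replicate 2. The comparison asks which genes differ between the sorted populations of mutant tissue. No library of normal embryos was analysed here. The labels do not say whether the 2 libraries of a population came from separate embryos or litters, so p-values measure only the spread between these libraries.

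The deposited table lists 36186 genes in normalized RPKM (NRPKM, reads scaled by gene length and library size, with a further scaling). The values are not counts, so the depth is known only through an estimate of the value of 1 read, the most common low value in short genes. By this estimate a single read in a gene of 1 kb was worth 0.859 and 0.818 NRPKM in the PTC2+ libraries (replicates 1 and 2). It was worth 0.645 and 0.877 NRPKM in the PTC2− libraries.

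For most of the genome the names in the table could not be relied on. Rps6 and Rpl13a, which encode ribosomal proteins made by every growing cell, were listed at 0 in all 4 libraries. Eif3a, a translation initiation factor, was listed at 0, 0.0958, 0 and 0 NRPKM in PTC2+ replicates 1 and 2 and PTC2− replicates 1 and 2. Among 828 constitutive genes outside 3 chromosome segments, 314 (37.9%, 95% exact binomial interval 34.6 to 41.3%) averaged 5 NRPKM or more, and 140 were at 0 in every library. Among 1493 genes of smell, taste and pheromone receptors, defensins and hair keratin-associated proteins outside the segments, 301 (20.2%, interval 18.2 to 22.3%) averaged 1 NRPKM or more. Of all 20241 protein-coding rows outside the segments, 31.6% averaged 5 NRPKM or more and 47.9% averaged 1 NRPKM or more. The constitutive share thus lay above that of all rows, and the restricted share below it. Inside the segments all 35 constitutive genes reached 5 NRPKM, and 0 of 57 such restricted genes reached 1 NRPKM (upper limit 6.27%).

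**Figure D1:**
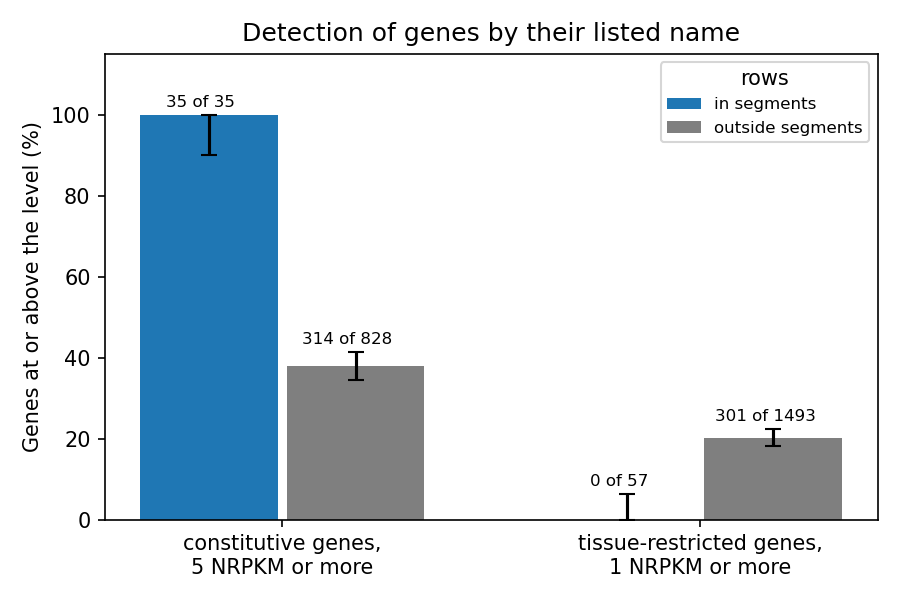
Bars give the percent of constitutive genes at 5 NRPKM or more and of tissue-restricted genes at 1 NRPKM or more, by the mean of all 4 libraries, for rows inside (blue) and outside (grey) the 3 segments; lines are 95% exact binomial intervals. Constitutive genes reached the level in 35 of 35 cases inside and 314 of 828 outside, and restricted genes in 0 of 57 inside and 301 of 1493 outside.

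The segments lie on chromosome 16 from Naa60 to Mrps6, on chromosome 19 from Ighmbp2 to Pygm and on chromosome 8 from Insr to Agpat5. They hold 1224 rows, 3.38% of the table. Of their 830 protein-coding rows 430 (51.8%) averaged 20 NRPKM or more, against 12.1% of those outside. The segments were chosen after the data were seen, from the mean of all 4 libraries, as runs rich in such genes. The share of constitutive genes inside them is therefore no independent test, whereas the restricted genes played no part in the choice. Restricted genes lie in clusters, so their interval is too narrow. Genes are described by name below only inside these segments, and other rows are counted as rows.

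The largest differences among the genes named inside the segments were higher in PTC2+ cells, that of Cd86 first. Cd86, a costimulatory molecule of antigen-presenting cells, stood at 63.3 and 55.5 NRPKM in the PTC2+ libraries and was listed at 0 in both PTC2− libraries. Unc93b1, which carries nucleic-acid-sensing Toll-like receptors to endosomes, averaged 243 ± 1.12 NRPKM (SD, n = 2) in PTC2+ and 6.75 ± 3.45 (SD, n = 2) in PTC2− cells. Nrros, a regulator of TGF-β activation in macrophages and microglia, averaged 270 ± 55.1 against 15.6 ± 4.04 NRPKM (SD, n = 2 each). The differences of the genes named as lower were smaller. Snai2, a transcription factor of mesenchymal cells, averaged 157 ± 21.7 NRPKM in PTC2+ against 404 ± 52.1 in PTC2− cells (SD, n = 2 each).

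The other genes named as higher in PTC2+ cells were Hcls1, Parp14, Stfa2l1, Cd200r1, Gas6, Cldn8 and Rtp4. Hcls1, an actin regulator of blood cells, averaged 69.1 NRPKM against 1.30 (log2 difference 4.98, SE 0.37). Parp14, a mono-ADP-ribosyltransferase induced by interferon, averaged 46.9 against 1.25 NRPKM (log2 difference 4.39, SE 0.34). Rtp4, another interferon-induced gene, stood at 27.2 and 18.7 NRPKM in PTC2+ and 0.820 and 1.67 NRPKM in PTC2− libraries. Cd200r1, an inhibitory receptor of myeloid cells, stood at 11.9 and 12.5 NRPKM in PTC2+ libraries and was listed at 0 in both PTC2− libraries. Stfa2l1, of the stefin A family of cysteine protease inhibitors, stood at 15.9 and 14.1 NRPKM and was listed at 0 in both PTC2− libraries; its near-identical copies lie next to it, so its reads may be shared. Gas6, the ligand of the TAM receptor kinases, averaged 272 against 20.8 NRPKM (log2 difference 3.69, SE 0.26). Cldn8, a tight-junction claudin of collecting duct epithelium, averaged 78.9 against 6.38 NRPKM (log2 difference 3.46, SE 0.29). The limma adjusted p of the 10 genes named as higher lay between 0.00192 and 0.00796 within the segments. Only Unc93b1 of these 10 lies in the shorter segments found with 40 NRPKM as the detection level. All 10 lost the call without PTC2+ replicate 1 or PTC2+ replicate 2, and Cd200r1 and Rtp4 also without PTC2− replicate 1.

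Robo2, the SLIT receptor that limits where the ureteric bud forms, averaged 26.1 NRPKM in PTC2+ and 61.5 in PTC2− cells (log2 difference -1.22, SE 0.21). Cd248, a surface protein of stromal fibroblasts and pericytes, averaged 80.1 against 178 NRPKM (log2 difference -1.14, SE 0.16). Epha3, an ephrin receptor, averaged 3.03 against 11.6 NRPKM, and Alcam, a cell adhesion molecule, 142 against 238 NRPKM. Zbtb20, a transcriptional repressor, averaged 36.9 against 67.9 NRPKM, and Cep97, a protein that restrains cilium assembly at the centriole, 28.5 against 53.4 NRPKM. Actn3, an actinin of fast muscle fibres, averaged 18.8 against 56.4 NRPKM, Rhod, a small GTPase of endosomes, 28.3 against 61.4 NRPKM, and Ctxn1 237 against 451 NRPKM. The limma adjusted p of the 10 genes named as lower lay between 0.00859 and 0.0470 within the segments, and all 10 lost the call when any 1 library was left out. Over all rows of the table, Epha3, Actn3, Robo2, Rhod, Cep97, Zbtb20 and Alcam did not pass (adjusted p 0.0508 to 0.0884).

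**Figure D2:**
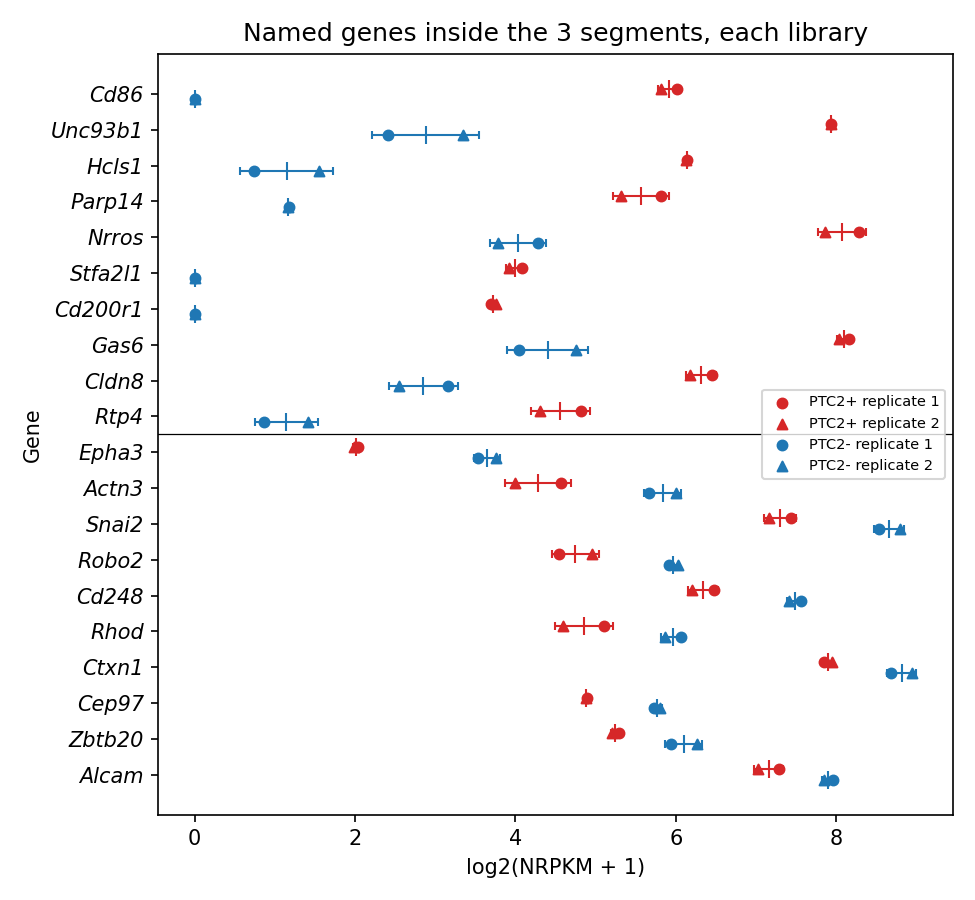
Each point is 1 library's log2(NRPKM + 1) for a named gene inside the segments, PTC2+ in red and PTC2− in blue, with circles for replicate 1 and triangles for replicate 2; ticks and lines give the mean and SD of the log2 values of the 2 libraries. Both PTC2+ libraries lie above both PTC2− libraries for the 10 genes above the line and below them for the 10 genes under it.

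Of 706 segment rows tested by limma, 78 changed at an adjusted p under 0.05 within the segments, 64 higher and 14 lower in PTC2+ cells. At an unadjusted p under 0.05 there were 190 rows, where 35.3 would arise with no effect. Of the 78 rows, 44 also passed the adjustment over the whole table. With no filter 36 segment rows changed, 33 higher and 3 lower. Without the mean-variance trend 32 changed, 31 higher and 1 lower. In 59.5% of segment rows the 2 populations did not overlap, against 33.3% by chance. The count rests on every library: it was 0 without PTC2+ replicate 1, 0 without PTC2+ replicate 2, 17 without PTC2− replicate 1 and 24 without PTC2− replicate 2, with 142, 151, 139 and 141 rows at an unadjusted p under 0.05. In simulated data with 40 of the 706 rows changed 2-fold, 47.6% of them were recovered, and a mean of 8.96% of the rows called were false, above the nominal 5%.

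Over the whole table, 11807 rows were tested by limma and 345 changed, 288 higher and 57 lower in PTC2+ cells. At an unadjusted p under 0.05 there were 2335 rows, against 590 with no effect. These rows differ between the populations, but which genes they measure is open outside the segments. The naming rule fixed beforehand took 20 rows over the whole table, and 1 of them, Cd86, lies in a segment. With no filter 0 rows changed, and without the mean-variance trend 200 did, 185 higher and 15 lower. Without PTC2+ replicate 1 or PTC2+ replicate 2, 0 rows changed (1757 and 1815 rows at an unadjusted p under 0.05), and 42 changed without PTC2− replicate 1 and 32 without PTC2− replicate 2. In 20 simulated tables with no effect, 7 gave at least 1 changed row.

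The rows listed as the hedgehog genes Gli1, Ptch1 and Hhip lie outside the segments, so they cannot check the labels. The row listed as Gli1, a transcription factor and target of the pathway, stood at 0.124 and 0.0478 NRPKM in PTC2+ replicates 1 and 2 and at 0 and 0.0385 NRPKM in PTC2− replicates 1 and 2, too low to be tested. The row listed as Ptch1 averaged 5.09 ± 1.28 NRPKM in PTC2+ and 6.69 ± 1.25 in PTC2− cells (SD, n = 2 each; limma adjusted p = 0.702). The row listed as Hhip, a hedgehog-binding target, averaged 33.6 ± 6.74 and 32.3 ± 0.0535 NRPKM (SD, n = 2 each; limma adjusted p = 0.948). A value for a whole gene also does not show a deletion of single exons.

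The 21 gene lists fixed beforehand met the same limit, since only 4 of their 154 tested rows lie in the segments. Of 19 lists with enough rows, 0 passed camera (adjusted p 0.478 to 0.953; 1 list at an unadjusted p under 0.05), 0 passed with an estimated correlation and 0 passed fry. Over all rows tested, 2 list rows were higher and 3 lower in PTC2+ cells, and adjusted over the list alone 5 were higher and 9 lower. The 4 members inside the segments did not pass within them. Boc, a hedgehog co-receptor, averaged 46.2 ± 6.93 NRPKM in PTC2+ and 72.9 ± 4.70 in PTC2− cells (SD, n = 2 each; limma adjusted p = 0.0822). Myh11, smooth muscle myosin, averaged 4.76 ± 2.42 and 6.63 ± 0.592 NRPKM. Cldn5, an endothelial claudin, averaged 44.1 ± 19.4 and 34.8 ± 0.224 NRPKM, and Mcm4, of the replicative helicase, 172 ± 23.3 and 209 ± 28.4 NRPKM (SD, n = 2 each; limma adjusted p 0.350 to 0.651 for Myh11, Cldn5 and Mcm4).

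Libraries of one population resembled each other more than those of the other population. Across the 11807 rows tested, Pearson's r of log2(NRPKM + 1) was 0.894 between the PTC2+ libraries and 0.913 between the PTC2− libraries. Between populations r lay between 0.806 and 0.827. Inside the segments, where r is across 706 rows, it was 0.942 and 0.964 within populations and 0.870 to 0.878 between them. These correlations are across genes, which are not independent replicates. The first principal component held 58.9% of the variance and separated PTC2+ from PTC2− libraries.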

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

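The fits on segment rows alone and the other detection levels were chosen after seeing the data; the other alternatives were planned. Of 305 alternative values of the 20 named genes, 217 kept their side of the threshold, 88 lost the call and 0 turned direction. The naming rule took only genes without overlap between the populations. A direction therefore could not turn with another pseudocount, filter or trend setting, with the block or with a library left out. The changed rows over the table (345) were 214 with a pseudocount of 0.1, 200 without a trend and 0 with no filter (2596 at an unadjusted p under 0.05 in limma). In the segments (78, with 64 higher and 14 lower), no filter gave 36, 33 and 3, no trend 32, 31 and 1, and segments found at 40 NRPKM 21, 18 and 3, where fewer rows were tested. Protein-coding segment rows alone gave 28 lower rows. For these settings other than fewer rows the cause was not tested. Leaving out 1 library gave 0 to 42 changed rows over the table and, in the segments, 0 to 24 changed, 0 to 24 higher and 0 to 1 lower; the lone library was taken to vary like the other population. Every one of the 20 named genes lost its call without PTC2+ replicate 1 or PTC2+ replicate 2 (adjusted p 0.122 to 0.230), with 1 library set against 2, while each log2 difference kept at least 76.9% of its size: that of Cd86 (5.91, adjusted p = 0.00192) was 5.82 and 6.01, and that of Unc93b1 (5.05) was 5.06 and 5.05. The genes named as lower held less well: all 10 also lost their call without PTC2− replicate 1 (adjusted p 0.0507 to 0.192) or PTC2− replicate 2 (0.0862 to 0.232), 9 with no trend, 7 with no filter, 4 with segments found at 10 NRPKM and 2 with a pseudocount of 0.1. Of the 10 named as higher, 2 lost it without PTC2− replicate 1, 0 without PTC2− replicate 2 and 0 with the other fits of this list. With a filter of 5 NRPKM 1 fixed list passed camera, the stromal list (adjusted p = 0.0119), whose rows lie outside the segments; the cause was not tested. The gap between the mean r within and between populations (0.0880) was 0.126 with a pseudocount of 0.1, 0.0665 with 5, 0.0425 with no filter and 0.145 with a filter of 5 NRPKM.

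By a number in its label each PTC2+ library is tied to 1 PTC2− library, and the labels do not say what the number marks. Deviations of same-numbered libraries correlated at 0.0229 across all rows tested and at 0.0926 across segment rows. With the replicate number as a block, 332 rows changed over the table and 97 in the segments, 75 higher and 22 lower; 74 of the 78 rows were called in both fits, and of the named genes Epha3 lost its call (adjusted p = 0.0560).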

Other observations

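Of the tests below, those of depth, genome builds, shallow sequencing and the myeloid list without relatives of named genes were chosen only after the result was seen. The 7 cell-type lists were written after the named genes were seen and leave those genes out, before the differences of their members were seen, except that the values of a few candidates had been seen and these were left out.

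In the myeloid list, 15 of 28 tested members were higher and 0 lower within the segments, and adjusted over the list alone 20 were higher and 1 lower. Klhl6 averaged 90.6 NRPKM in PTC2+ and 24.9 in PTC2− cells. Nfkbiz, an inducible regulator of NF-κB, stood at 124 and 122 NRPKM in the PTC2+ libraries and 36.1 and 28.8 in the PTC2− libraries. Il10rb, a chain of the interleukin 10 receptor, averaged 33.2 and 6.93 NRPKM, and Stxbp2, which serves granule release, 284 and 121 NRPKM. Tnfsf13b, a B-cell survival factor, went the other way, with 3.03 and 7.75 NRPKM (limma adjusted p = 0.134). The list stood above other segment rows by camera with the preset correlation (adjusted p = 6.6e-09) and did not pass with an estimated correlation (adjusted p = 0.140). The estimate was -0.036, below the preset 0.01, so a higher correlation does not account for this. With an estimated correlation camera takes its degrees of freedom from the 4 libraries, so it has little power here. Fry, which tests the list against no change, gave an adjusted p = 0.00105. The list holds relatives of named genes. Without its Stfa, Cd200r and Cd80 members, 12 of 22 members were higher and 0 lower (camera adjusted p = 3.97e-07; adjusted p = 0.185 with an estimated correlation; fry adjusted p = 0.00817). In the interferon list 3 of 6 members were higher, Dtx3l, Il10rb and Ifngr2 (4 adjusted over the list alone, camera adjusted p = 0.00549, fry adjusted p = 0.00817, adjusted p = 0.290 with an estimated correlation). Il10rb and Ifngr2 are in both lists, so the interferon result is not separate from the myeloid one. Parp9, a relative of the named gene Parp14, stayed in the interferon list.

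The other lists did not pass camera on the 3 segments. On the shorter segments found at 40 NRPKM the epithelial list passed too, upward, with 4 rows (camera adjusted p = 0.0440), beside the myeloid list (camera adjusted p = 0.000176). Of 18 mesenchyme and matrix members, 1 was higher and 0 lower (0 adjusted over the list alone; camera adjusted p = 0.366), of 10 endothelial and basement membrane members 1 was higher (1 adjusted over the list alone; camera adjusted p = 0.892), and of 15 proliferation members 0 changed either way (camera adjusted p = 0.458). Of 10 epithelial members 1 was higher (4 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.278), with a fry adjusted p = 0.0141 and an adjusted p = 0.572 with an estimated correlation. Of 7 neural members 0 changed (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.941).

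A candidate explanation for the higher genes of the myeloid list is myeloid cells in the PTC2+ sort. The list was higher, which this explanation predicts, by camera with the preset correlation (adjusted p = 6.6e-09, and 9.43e-10 before adjustment), with and without relatives of named genes. It did not pass with an estimated correlation (adjusted p = 0.140 and 0.185). Of its 28 members 21 reached 1 NRPKM in both PTC2− libraries too, and the labels name no step that would remove leukocytes. Rela (56.4 and 69.0 NRPKM) and Cd47 (69.0 and 80.8 NRPKM) stood high in PTC2− replicates 1 and 2. The list is therefore not specific to myeloid cells, and its rise cannot single them out. An immune response within mesenchymal cells stays open, since the mesenchyme list, which leaves out the named genes, did not pass as lower (limma camera adjusted p = 0.366; 0.209 before adjustment), though 12 of its 18 members lay below 0 and the named genes Snai2 and Cd248 were lower (limma adjusted p = 0.00859 and 0.0148). A biological difference between PTC2+ and PTC2− cells was not tested apart from cell makeup. Shallower PTC2− libraries are argued against only for a set of 14 well-covered list members, given after a wider set. Of 40 genes (the myeloid and interferon lists with the named immune genes Cd86, Unc93b1, Nrros, Hcls1, Parp14, Stfa2l1, Cd200r1 and Rtp4), 24 averaged 10 reads in 1 kb or more over all libraries. All 24 were higher in PTC2+ cells against either PTC2− library, with a median log2 difference of 1.46 against replicate 1 and 1.33 against replicate 2. The lower of the 95% limits was 0.886. At most, 1 read was worth 0.10 more, in log2, in a PTC2− than in a PTC2+ library. Since NRPKM is scaled by library size, that ratio is not the shift that depth would give. The set of 24 holds genes named for their differences, and some reach the coverage through PTC2+ libraries alone, so it cannot decide. Of the list members without named genes, 14 reached 10 reads in 1 kb in both PTC2− libraries, and all 14 were higher in PTC2+ cells, with a median log2 difference of 0.90 against replicate 1 (95% limits 0.48 to 1.30) and 1.13 against replicate 2 (0.24 to 1.36). For genes below that coverage it stays open, since 1 of the 2 PTC2− libraries was shallower than both PTC2+ libraries: 1 read in 1 kb was worth 0.645 NRPKM in PTC2− replicate 1, the finest step of all, and 0.877 in PTC2− replicate 2, the coarsest. The pattern remains a hypothesis, found and tested on the same libraries.

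Outside the segments 140 of 828 constitutive genes were at 0 in every library, while 55.8% averaged 1 NRPKM or more. Beside those at or near 0 stood sense-receptor genes with reads. Shallow sequencing is argued against by 69 of 1493 restricted genes outside the segments at 20 NRPKM or more. That share was 4.62%, against 12.1% of all protein-coding rows there. A shift of values by a constant number of rows is argued against by the constitutive genes outside the segments. Over lags of up to 200 rows, at most 14.9% of them met a value of 20 NRPKM or more, against 16.7% unshifted. A candidate explanation is that reads placed on mm9 were counted at gene positions of GRCm38, which could leave names intact near chromosome starts, where positions of both builds can still agree. At 20 NRPKM the 3 runs begin by protein-coding row 5 of their chromosomes, but at 10 NRPKM a run begins as late as row 1314, and the level was chosen after seeing the data, so this cannot be told apart from dense gene regions. The run on chromosome 16 spans 533 protein-coding rows, so it is not confined to the chromosome start. Where runs end was not examined. No biological explanation was tested, since all 4 libraries show the pattern.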
